A study of Mus musculus and Homo sapiens with 15 samples.

How the data were processed

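RNA was measured by sequencing of libraries made with a stranded mRNA kit (KAPA) from TRIzol-extracted RNA, per the labels' protocols, in 6 MCF7 libraries and 9 libraries of 67NR tumours. The authors deposited a table of counts per gene symbol for each species, with a column per library. The submitters' processing notes name CASAVA, STAR 2.5.2b, featureCounts and DESeq2 without giving their roles, and name the human build hg19. The mouse build, the annotation and the strand setting of the counting are not given in the sources used here, and no coordinates were used. Each table also held the length of each gene in bases, per the file headers, which was used only to check for length trends.

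The tables held 27140 human and 24391 mouse genes. Total counts were 19071704 and 18076596 with shCtrl, 15869859 and 15046308 with shEZH24, and 15621526 and 14625728 with shEZH2A. They were 6328610, 7199960, 9040688 and 6158127 for GSK503 replicates 1 to 4, and 7840494, 8402235, 10232430, 11367570 and 12098880 for vehicle replicates 1 to 5. Between 18331 and 18766 genes had a count in an MCF7 library and between 16385 and 16920 in a tumour library. The 10 highest genes took 4.40% to 4.86% of the counts in MCF7 and 5.57% to 11.0% in the tumours, where the ribosomal RNA gene Rn45s took 0.426% to 6.13%. A count of 1 equalled 0.0524 to 0.0684 CPM (counts scaled to library size) in MCF7 and 0.0827 to 0.162 in the tumours, and a gene with 0 counts in a library could have had up to 0.157 to 0.205 CPM or 0.248 to 0.487 CPM (3 counts). Counting intervals (95%) and these floors cover counting error only.

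Counts were normalised with TMM factors, filtered with filterByExpr and fitted in edgeR 4.0.16 under R 4.3.3 with the robust quasi-likelihood model. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. MCF7 was 1 fit of 3 groups, with contrasts for the mean of both hairpins against shCtrl, for each hairpin against shCtrl and between the hairpins. All adjusted p-values of genes come from these edgeR fits unless another tool is named. Library pairs within a group were compared by chi-square per degree of freedom, where counting noise alone gives 1.

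The tumour test departs from the design set at the start, which compared 4 GSK503 with 5 vehicle libraries. GSK503 replicates 1 and 4 differed by 1.13 per degree of freedom, so their counts were summed to 1 sample and the test compared 3 with 5 samples. The counts of genes under other groupings had been seen when this was settled, and the choice rests on the chi-square values. The comparison of all 9 libraries is given beside it. The MCF7 pairs differed as little but had no other pair in their group to be set against, and were kept as 2 samples.

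Lists of genes were fixed before the data were examined, 22 for human and 32 with enough tested members for mouse, and tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of that organism. Camera was run again with an estimated correlation, and fry was run beside it. List members were also counted with p-values adjusted over the list alone. Genes tested in both species were matched by symbol, and the overlap of calls was tested with Fisher's exact test, 2-sided. Chance agreement between hairpins that share controls was taken from 20 simulated sets of unchanged groups.

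The genes named in the text were set by a rule. It takes EZH2, EZH1, EED, SUZ12, IFNAR1, IFNAR2, JAK1, TYK2, STAT1, STAT2 and IRF9, the 10 largest changes per direction among called genes with a mean of at least 1 CPM, and the 4 members with the smallest p of each list described. The largest changes had to pass with each hairpin in MCF7 and not overlap between groups in the tumours, and symbols with set beginnings or endings typical of clones, loci and small RNAs (such as LOC, LINC, MIR or Rik) were left out, which does not catch every pseudogene (ACTG1P20). For the difference between hairpins, the 5 largest per direction were taken. Genes named outside the rule are marked as chosen after their values were seen.

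The alternatives were RLE and upper-quartile factors, no filter or a filter at 1 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, a fit without robust estimation, an adjusted p under 0.01, an absolute log2 fold change of at least 1, a fit per hairpin, both hairpins as 1 group, a prior count of 0.5, the replicate number as a block, and each sample left out in turn. Alternatives added after the data were seen were the tumour libraries as deposited, vehicle replicates 3 and 5 summed as well, the same with GSK503 replicates 1 and 4 left out, and removal of the length trend with a loess (span 0.5) per library. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups.

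The fits were tested on simulated data with 200 changed genes. In MCF7 the contrast of both hairpins recovered 77.6%, 98.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold and called 8 unchanged genes. In the tumours the fit recovered 0%, 5.97% and 68.2% and called 1 unchanged gene, so moderate changes there mostly go undetected. A raised list was recovered in both species with 0 other lists called. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls unchanged lists whose members vary together, as interferon-stimulated genes did in the tumours (estimated correlation 0.503). Figures were drawn with matplotlib 3.10.9.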

Results

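Gene expression was measured by RNA sequencing in a human cell line and in mouse tumours in which EZH2, the catalytic subunit of the Polycomb complex PRC2, was depleted or inhibited. MCF7, an established oestrogen-dependent human breast cancer line, carried a control short hairpin RNA (shCtrl) or either of 2 hairpins against EZH2, shEZH24 and shEZH2A, with 2 libraries per group. Tumours of 67NR, a mouse mammary carcinoma line, came from BALB/c mice that had received the EZH2 inhibitor GSK503 (4 libraries) or its Captisol vehicle (5 libraries). The title of the series names suppression of interferon alpha/beta and STAT2 signalling by EZH2, and both comparisons ask how interferon and immune genes stand when EZH2 is reduced. Total counts per library ranged from 14625728 to 19071704 in MCF7 and from 6158127 to 12098880 in the tumours. The libraries of each MCF7 pair differed by little more than counting noise (chi-square per degree of freedom 1.13 to 1.20), and the labels do not say that they came from separate cultures. The MCF7 p-values therefore measure only the spread between these libraries, which may be technical.

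EZH2 mRNA was lower with both hairpins. It stood at 106 ± 0.145 CPM (SD, n = 2) with shCtrl, 53.7 ± 0.00306 CPM with shEZH24 and 54.1 ± 0.580 CPM with shEZH2A (n = 2 each), a log2 fold change of -0.98 (SE 0.037, adjusted p = 3.09e-38). The log2 fold change was -0.99 with shEZH24 and -0.97 with shEZH2A. EZH1, the paralogue of EZH2, did not pass the test (log2 fold change -0.03, adjusted p = 0.671). EED and SUZ12, the core partners of EZH2 in PRC2, rose slightly, by log2 fold changes of 0.35 and 0.24, while JARID2, an accessory PRC2 protein, fell by 0.83 on the log2 scale. Of the 14 genes on the list of PRC2 and its partners, 6 rose and 4 fell, also adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.841).

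Interferon-stimulated genes rose in MCF7 cells carrying either EZH2 hairpin. Of the 50 members tested on that list, 49 rose and 0 fell, 49 also adjusted over the list alone, with a median log2 fold change of 3.06 (adjusted p = 7.97e-23, and adjusted p = 0.0249 with an estimated correlation). ISG15, a ubiquitin-like protein, went from 35.02 ± 1.20 CPM with shCtrl to 633 ± 0.0130 with shEZH24 and 490 ± 23.5 with shEZH2A (SD, n = 2 each). OAS3, a synthetase activated by double-stranded RNA, went from 65.7 ± 2.97 CPM to 940 ± 1.52 and 770 ± 7.23. IFIT1, which binds foreign RNA, went from 4.05 ± 0.202 CPM to 334 ± 1.58 and 243 ± 7.13.

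The transcription factors that carry the interferon alpha/beta signal rose as well. STAT1 had a log2 fold change of 2.29 (SE 0.022), IRF9 of 2.18 (SE 0.035) and STAT2 of 0.55 (SE 0.032). STAT2 went from 86.7 ± 1.56 CPM to 137 ± 1.93 with shEZH24 and 117 ± 1.42 with shEZH2A (SD, n = 2 each, adjusted p = 1.61e-26). Upstream of them, the kinases TYK2 and JAK1 rose by log2 fold changes of 0.14 and 0.08 and the receptor chain IFNAR2 by 0.28, whereas the receptor chain IFNAR1 had a log2 fold change of 0.01 that did not pass (adjusted p = 0.846). JAK1 was no longer past the threshold without shCtrl replicate 1 (log2 fold change 0.057, adjusted p = 0.0568), nor IFNAR2 without shCtrl replicate 2 (0.20, adjusted p = 0.0772). On the list of type I interferon signalling and sensing components, 15 of 19 members rose and 2 fell, also adjusted over the list alone, with a median of 0.31 (adjusted p = 0.00185, but adjusted p = 0.164 with an estimated correlation).

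Genes of antigen presentation were mostly higher. On the MHC class I list, 21 of 23 members rose and 2 fell, also adjusted over the list alone, with a median log2 fold change of 1.497 (adjusted p = 1.1e-07, and adjusted p = 0.0876 with an estimated correlation). B2M, the light chain of class I molecules, rose by a log2 fold change of 1.80, HLA-C, a heavy chain, by 1.53, and TAP2, part of the peptide transporter, by 3.12. CALR, a chaperone of the endoplasmic reticulum, fell by 0.42 on the log2 scale. On the MHC class II list, 9 of 10 members rose and 0 fell, also adjusted over the list alone, with a median of 2.14 (adjusted p = 0.003, and adjusted p = 0.222 with an estimated correlation). CD74, the invariant chain, rose by 2.91 from 0.642 CPM with shCtrl, and CTSS, a protease that processes it, by 1.95. Counts of individual HLA genes are uncertain, because near-identical family members can share reads.

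**Figure D1:**
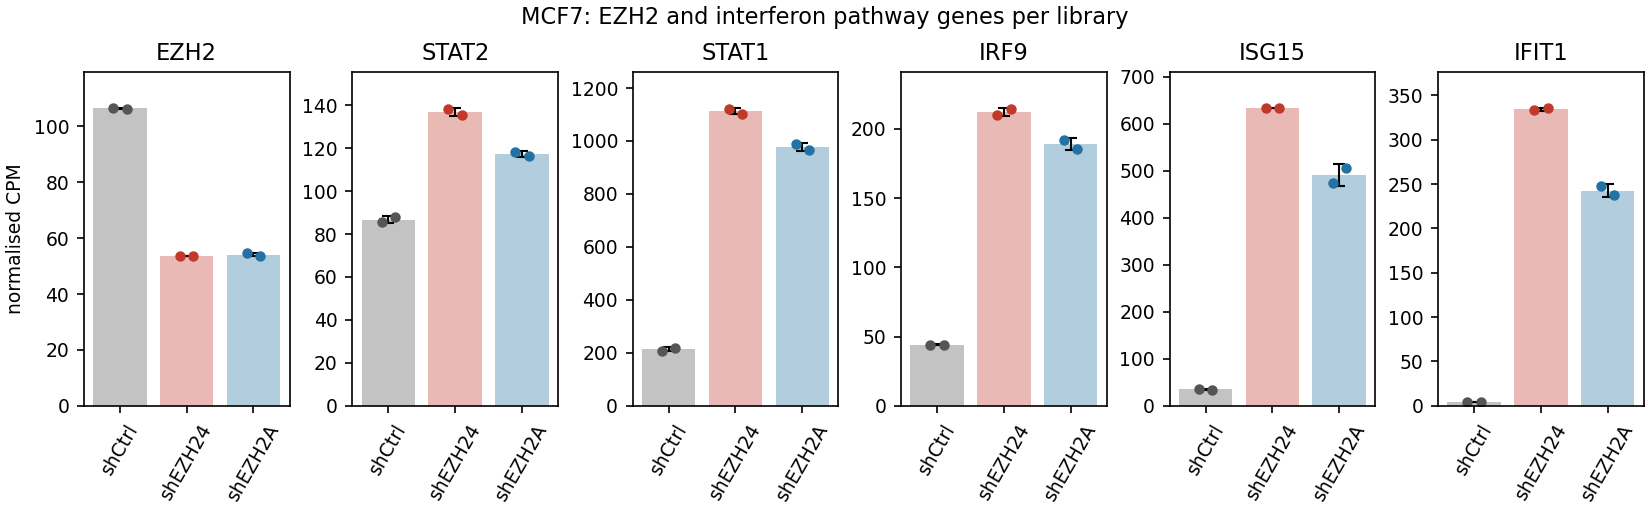
Normalised CPM (y axis, starting at 0) of EZH2, STAT2, STAT1, IRF9, ISG15 and IFIT1 in MCF7 with shCtrl, shEZH24 and shEZH2A. Points are libraries, bars are group means and error bars are SDs (n = 2), and EZH2 goes from 106 to 53.7 and 54.1 CPM while the other genes are higher with both hairpins.

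Among genes with a mean of at least 1 CPM, the largest increases past the threshold with both hairpins included several genes almost silent in shCtrl, for which ratios are given with their 95% counting interval. CGA, the alpha subunit of the glycoprotein hormones, had 2 counts over both shCtrl libraries and a ratio of 838 (232 to 6923). The ratio was 131 (44.5 to 635) for XAF1, 124 (34.2 to 1029) for IFI44L, 103 (35.01 to 500.4) for IFI44, 82.9 (22.7 to 688) for DSCR8 and 61.9 (16.9 to 515) for RARRES3, each with 2 or 3 shCtrl counts. The largest increases also included DDX60, IFI27, IFIT1 and OAS2, with log2 fold changes of 6.34, 6.32, 6.13 and 5.38. Among genes with a mean of at least 1 CPM, the largest decreases past the threshold with both hairpins included CHAC1, a glutathione-degrading enzyme (-3.89), the transcription factor FOSB (-3.75), HAR1B (-3.57), CTGF, a matricellular protein (-3.55), the somatostatin receptor SSTR5 (-3.35), ADM2 (-3.33), LDLRAD4 (-3.26), AMTN (-3.24), MUC16 (-3.19) and SLC7A11, a cystine transporter (-3.02). HAR1B overlaps a gene on the opposite strand, and its reads cannot be told apart from those of its partner where counting ignored strand, which the sources used here do not say.

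Genes of hormone response and luminal identity were mostly lower. On the oestrogen response list, 18 of 29 members fell and 7 rose, also adjusted over the list alone, with a median of -0.36 (adjusted p = 0.00639, and adjusted p = 0.237 with an estimated correlation). CCND1, a cyclin that drives entry into S phase, fell by 0.89 on the log2 scale, STC2 by 1.53 and NRIP1, a nuclear receptor corepressor, by 0.87, while CA12 rose by 1.45. On the luminal list, 14 of 20 members fell and 5 rose, also adjusted over the list alone, with a median of -0.16 (adjusted p = 0.0149, and adjusted p = 0.164 with an estimated correlation). They included ESR1, the oestrogen receptor, which went from 711 ± 0.796 CPM to 415 ± 4.29 and 422 ± 2.39 (SD, n = 2 each), SPDEF (-1.33) and ERBB3 (-0.96).

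Stress and growth genes moved too. On the unfolded protein response list, 17 of 21 members fell and 4 rose, also adjusted over the list alone, with a median of -0.36 (adjusted p = 0.00194, and adjusted p = 0.164 with an estimated correlation), among them ASNS (-2.53), TRIB3 (-1.38) and ATF4 (-0.83), which amino acid shortage as well as unfolded proteins can induce. NF-kB targets rose in 12 of 18 cases and fell in 2, with a median of 0.86, including IER3 (1.48), TNFAIP3 (1.22) and NFKB2 (0.86), with adjusted p = 0.00655 and adjusted p = 0.164 with an estimated correlation. DNA replication genes rose in 23 of 33 cases and fell in 5, with a median of only 0.23, including FEN1 (0.77), RRM2 (0.72) and PCNA (0.67), with adjusted p = 0.000644 and adjusted p = 0.15 with an estimated correlation. The counts of both lists were the same adjusted over the list alone.

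Of the remaining lists past the threshold, chemokines rose in 7 of 8 cases and fell in 1 (adjusted p = 0.0217), mitotic genes rose in 19 of 30 and fell in 6 (adjusted p = 0.0217), and hypoxia and glycolysis genes rose in 15 of 28 and fell in 5 (adjusted p = 0.0235). Targets of p53 and CDK inhibitors fell in 14 of 24 cases and rose in 4 (adjusted p = 0.0149). With an estimated correlation these gave adjusted p = 0.24, 0.317, 0.25 and 0.164, so that 13 of the 22 human lists passed with the preset correlation and 1, the interferon-stimulated genes, with an estimated correlation. Adjusted over the list alone, 17 hypoxia and glycolysis genes rose, and the other 3 lists kept their counts. For some lists that failed with it, the estimated correlation was below the preset 0.01, such as MHC class I (-0.031) and DNA replication (-0.012). For others it was above, such as mitotic genes (0.081). A higher correlation among members thus cannot account for the larger p-values of the former. Nor can it for the interferon-stimulated list, whose estimated correlation was -0.017. Its unadjusted camera p went from 3.62e-24 to 0.00113. The fall from 13 lists to 1 therefore does not measure correlation among members alone.

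Developmental genes, many of which are classical PRC2 targets, did not move as a group where enough counts allowed a test. Of the 84 developmental transcription factors listed, 46 passed the filter. Of these 46, 15 rose and 17 fell, also adjusted over the list alone (adjusted p = 0.841). Members with too few counts were not tested, and the result does not cover them. ASCL1, a neuronal fate factor, rose from 7.02 ± 0.247 CPM to 65.9 ± 5.05 and 66.0 ± 0.486 (SD, n = 2 each), and GATA4 rose by a log2 fold change of 2.30, whereas FOXC1 (-0.93) and RUNX1 (-0.73) fell. Of the 39 HOX genes listed, 21 were tested. Of these 21, 4 rose and 6 fell, 3 and 5 adjusted over the list alone (adjusted p = 0.894). Immediate early and heat shock genes rose in 9 of 25 cases and fell in 13 (adjusted p = 0.211), and FOS (-1.65), EGR1 (-1.94) and KLF4 (-1.52) were among those that fell. The other lists that did not pass gave adjusted p = 0.0647 for basal identity (3 of 14 rose, 10 fell), 0.175 for epithelial-mesenchymal transition (2 of 22 rose, 9 fell), 0.199 for cholesterol synthesis (11 of 23 rose, 5 fell), 0.704 for germline genes (0 of 3 rose, 1 fell) and 0.704 for markers of other cell types (3 of 7 rose, 2 fell). These counts were the same adjusted over the list alone. The median and the direction of the test differed in sign for PRC2 and germline genes, as did the mean and the test for PRC2 and developmental factors. The basal list passed without shCtrl replicate 2, shEZH24 replicate 2 or shEZH2A replicate 1 (adjusted p = 0.0498, 0.0456 and 0.0403).

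**Figure D2:**
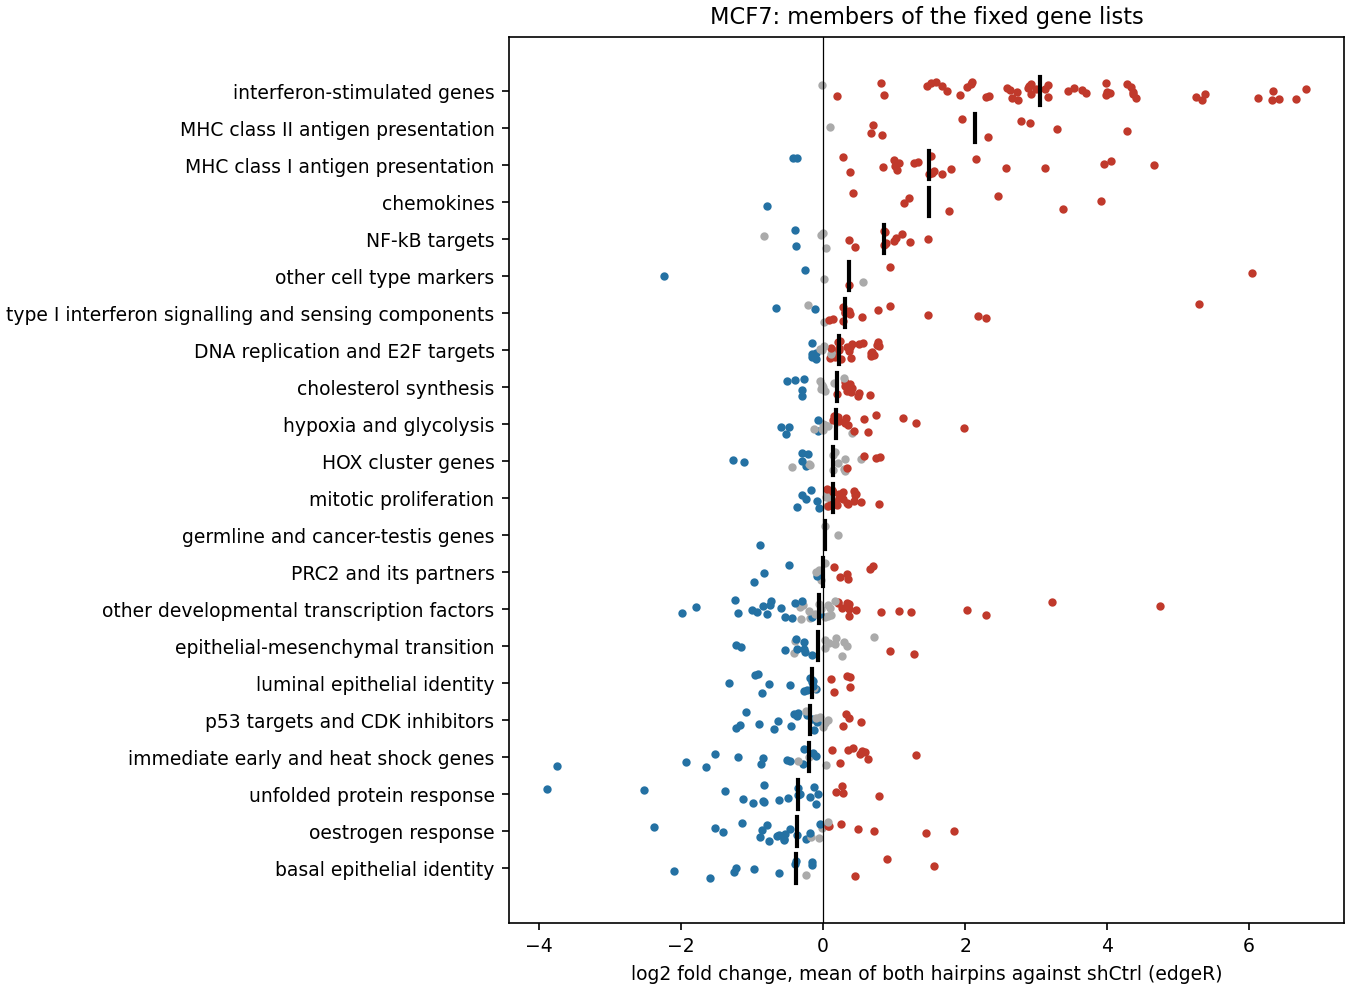
Log2 fold change (x axis, mean of both hairpins against shCtrl) of each tested member of the 22 human gene lists (y axis, ordered by median). Red points passed the test upward, blue points downward and grey points did not pass, black bars are list medians, and the interferon-stimulated genes have the highest median, 3.06.

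Over all genes, 9809 of the 14566 tested passed the threshold in MCF7 (67.3%), 4927 upward and 4882 downward, in edgeR's quasi-likelihood test. With an absolute log2 fold change of at least 1 as well, 619 were higher and 552 lower. Longer genes were slightly lower with both hairpins (Spearman's rho -0.188 across genes, which are not independent replicates), from a median log2 fold change of 0.11 in the fifth of genes with the shortest lengths to -0.15 in that with the longest, so small changes of long or short genes carry this trend.

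The hairpins gave similar profiles, with a stronger interferon response to shEZH24. The same 4122 genes rose and 4053 fell with each hairpin, where independent lists would share 1455 and 1411, and 2 passed in opposite directions. The log2 fold changes had a Pearson's r of 0.955 and a covariance of 0.447, against 0.469 and 0.0121 in simulated unchanged groups that shared the shCtrl libraries, in which at most 1 gene passed with both. The simulated spread came from library pairs that differ by little more than counting noise. A shift common to both shCtrl libraries was not simulated and would also raise the agreement. The shCtrl libraries were not split between the hairpins, which would leave 1 for each, and part of the excess of shared calls over independent lists may come from sharing them. In the test of the difference, 147 genes were higher with shEZH24 and 179 with shEZH2A. Of the 50 interferon-stimulated genes, 41 were higher with shEZH24 and 0 lower, 48 adjusted over the list alone, with a median difference of 0.35 (adjusted p = 4.53e-36, and adjusted p = 0.0125 with an estimated correlation). MHC class I genes were higher in 15 of 23 cases, 17 adjusted over the list alone (median 0.26, adjusted p = 3.53e-12, and adjusted p = 0.045 with an estimated correlation). Immediate early and heat shock genes were lower with shEZH24 in 12 of 25 cases, 14 adjusted over the list alone (median -0.24, adjusted p = 8.1e-13, but adjusted p = 0.122 with an estimated correlation). EZH2 itself did not differ detectably between the hairpins (log2 difference -0.012, 95% interval -0.12 to 0.092, adjusted p = 0.967).

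Among genes with a mean of at least 1 CPM, those most in favour of shEZH24 were IFI44 (log2 difference 1.24), ACTG1P20 (1.13), a pseudogene whose reads its parent gene can share, IFI44L (1.08), XAF1 (1.07) and PDIA2 (1.04). TEX19 (-1.43), FCGR2B (-1.38), FOXN1 (-1.003), ERFE (-0.89) and ARC (-0.87) were lower with shEZH24. These last 5, ACTG1P20 and PDIA2 had a mean of 3.65 CPM (ARC) or less in each group, and the 7 lost the call without shEZH24 replicate 1 (adjusted p up to 0.341, TEX19), shEZH24 replicate 2 (up to 0.287, FOXN1) or shEZH2A replicate 1 (up to 0.517, ACTG1P20). Without shEZH2A replicate 2 all but ACTG1P20 and ERFE lost it (up to 0.187, TEX19). Without shEZH24 replicate 2, 204 genes differed in place of 326.

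In the 67NR tumours, GSK503 replicates 1 and 4 differed by little more than counting noise (chi-square per degree of freedom 1.13), whereas every other pair of GSK503 libraries differed by 36.2 to 165. They were counted as 1 sample, which left 3 GSK503 and 5 vehicle samples. Vehicle replicates 3 and 5 were also close (3.03, against 21.9 to 116 for the other vehicle pairs) and were kept as 2 samples, although with them summed as well, a grouping added after the data were seen, edgeR called 0 genes (1486 at unadjusted p under 0.05). Ezh2 mRNA, which an enzyme inhibitor need not change, was 65.2 ± 26.2 CPM (SD, n = 3) with GSK503 and 88.0 ± 28.7 CPM (n = 5) with vehicle, a difference that did not pass (log2 fold change -0.43, adjusted p = 0.578).

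**Figure D3:**
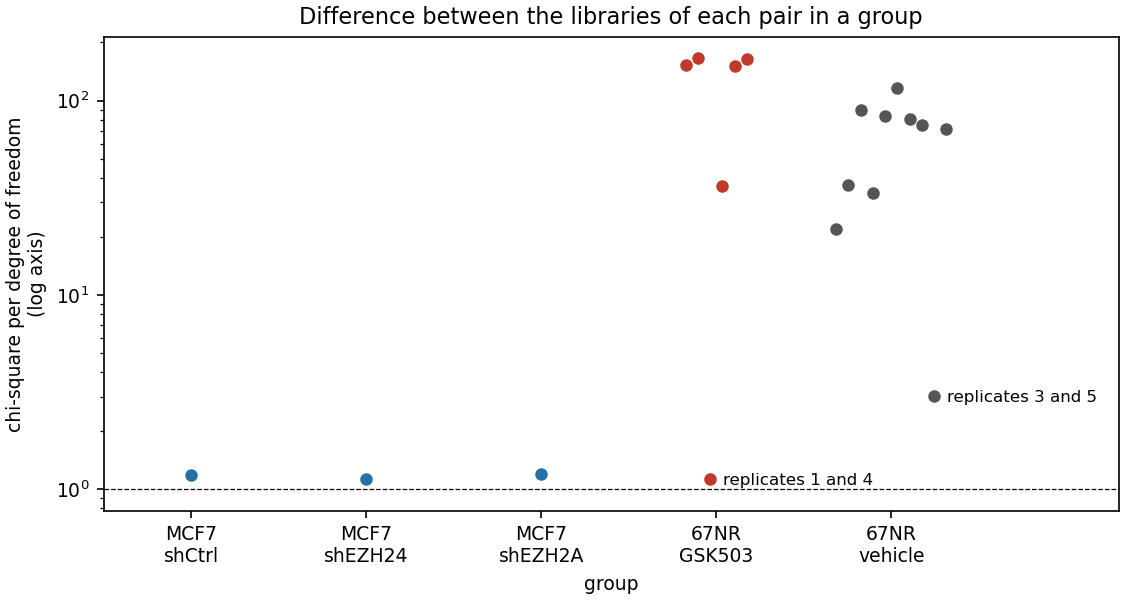
Chi-square per degree of freedom (y axis, log axis) between the libraries of each pair within a group (x axis), where the dashed line at 1 is counting noise alone. GSK503 replicates 1 and 4 lie at 1.13, beside the MCF7 pairs at 1.13 to 1.20, and vehicle replicates 3 and 5 at 3.03.

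Lymphocyte genes were higher in GSK503 tumours. On the T cell list, 19 of 20 members rose, 20 adjusted over the list alone, with a median log2 fold change of 5.45 (adjusted p = 9.48e-22, but adjusted p = 0.228 with an estimated correlation). Itk, a kinase of T cell receptor signalling, stood at 175 ± 175 CPM (SD, n = 3) with GSK503 and 5.51 ± 3.13 CPM (n = 5) with vehicle, and the costimulatory receptors Cd28 and Icos rose by log2 fold changes of 4.19 and 2.89. On the B and plasma cell list, 10 of 14 members rose, 13 adjusted over the list alone, with a median of 6.30 (adjusted p = 1.47e-11, but adjusted p = 0.228 with an estimated correlation), among them Blk (6.25) and Jchain (5.75). On the cytotoxic lymphocyte and NK cell list, 7 of 20 members rose, 15 adjusted over the list alone, with a median of 1.95 (adjusted p = 3.52e-14, but adjusted p = 0.228 with an estimated correlation). Klrd1, an NK cell receptor, stood at 19.5 ± 5.99 CPM with GSK503 and 4.03 ± 1.10 with vehicle (SD, n = 3 and 5), and Nkg7 (2.83), Ctsw (3.18) and Tbx21 (2.40) rose with it. On the regulatory T cell and checkpoint list, 7 of 16 members rose, 11 adjusted over the list alone (median 1.96, adjusted p = 2.97e-10, but adjusted p = 0.228 with an estimated correlation), including Cd274, which encodes PD-L1 (1.76).

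GSK503 replicates 1 and 4 stood apart from the rest for these lists. The mean log2 CPM of the T cell list was 7.77 and 7.81 in them, 4.23 and 4.29 in GSK503 replicates 2 and 3, and 0.76 to 1.69 in the vehicle libraries, and for the B cell list it was 7.26 and 7.27, 3.70 and 3.48, and -0.11 to 1.71. The cytotoxic list means were 3.81 and 3.80, 3.07 and 4.11, and 1.70 to 2.55. Without replicates 1 and 4, a comparison added after the data were seen, the T cell median was 3.10 with 19 of 20 members past the threshold, the B cell median 3.66 with 6 of 14, the cytotoxic median 1.85 with 7 of 20, and the regulatory T cell and checkpoint median 1.68 with 4 of 16.

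Among called genes with a mean of at least 1 CPM, the largest increases included Dapl1 and Cd40lg, each with 2 counts over the vehicle libraries and ratios of 575 (159 to 4759) and 345 (94.9 to 2858), then Vipr1, Nsg2, St8sia1, Dtx1, Fcer2a, Pou2af1, Cd79b and Cd19, with log2 fold changes from 8.22 to 6.93. Without GSK503 replicates 1 and 4, those of Fcer2a and Cd19 were 4.39 and 4.44. Cd79b, a chain of the B cell receptor, stood at 98.1 ± 160.1 CPM with GSK503 and 0.730 ± 0.300 with vehicle (SD, n = 3 and 5). In all, 224 genes rose and 1 fell of the 13365 tested in edgeR's quasi-likelihood test. The gene that fell was Skp2, a subunit of a ubiquitin ligase (log2 fold change -1.02, SE 0.18). Of all 13365 genes, 7.86% were higher and 3.97% lower in every GSK503 sample than in every vehicle sample, and 2100 had an unadjusted p under 0.05. Chance gives 1.79% in each direction if the 8 samples are independent, which vehicle replicates 3 and 5 may not be. Genes that vary together can also raise these shares. With all 9 libraries as separate samples, 803 genes rose and 35 fell, and 222 of the 224 were among those that rose.

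The tumour calls lay close to the threshold, with adjusted p = 0.0459 for most named genes. Without vehicle replicate 1 the comparison gave 1 gene, and without vehicle replicate 2, 3, 4 or 5 it gave 0 each in edgeR (1944, 1473, 1942 and 1480 at unadjusted p under 0.05). Without GSK503 replicate 2 it gave 693, without GSK503 replicate 3 it gave 452, and without replicates 1 and 4 together 167, of which 147 of the higher genes were shared with the 224. The genes named here that passed had an adjusted p of 0.0577 (H2-DMb1 and Icos, without vehicle replicate 1) to 0.16 (Cd19, without vehicle replicate 5) with a vehicle library left out. Without GSK503 replicates 1 and 4, Fcer2a (adjusted p = 0.143), Cd19 (0.145), H2-Aa (0.0646), H2-Ab1 (0.0813) and Gbp8 (0.0992) did not pass, nor did H2-Ab1 (0.0513) and Gbp8 (0.0545) without GSK503 replicate 3. DESeq2 gave 696 genes and limma-voom 1.

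The antigen presentation and interferon lists had positive median log2 fold changes, and outside MHC class II few members passed the threshold. On the MHC class II list, 8 of 12 members rose, 11 adjusted over the list alone, with a median of 2.26 (adjusted p = 1.68e-11, but adjusted p = 0.228 with an estimated correlation). H2-Aa stood at 952 ± 384 CPM with GSK503 and 193 ± 81.8 with vehicle (SD, n = 3 and 5), with H2-Ab1 (2.21) and H2-DMb1 (2.25) beside it. On the MHC class I list, 1 of 24 members rose, 20 adjusted over the list alone, with a median of 0.82 (adjusted p = 1.32e-11, but adjusted p = 0.284 with an estimated correlation), and that member was Tap1 (2.15), part of the peptide transporter. Of 55 interferon-stimulated genes, Sp110 (2.75) alone rose past the threshold, 32 adjusted over the list alone, with a median of 1.23 (adjusted p = 4.46e-12, but adjusted p = 0.374 with an estimated correlation), and 6 of the 56 splits of the 8 samples into 3 and 5 gave a camera p as small. On the interferon gamma list, Gbp8 (1.84) passed of 27, 17 adjusted over the list alone, with a median of 1.34 (adjusted p = 1.13e-08, but adjusted p = 0.284 with an estimated correlation). Near-identical H2 and Gbp family members can share reads.

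Stat1, Stat2 and Irf9 did not pass in the tumours, with log2 fold changes of 1.97, 1.24 and 1.62 (adjusted p = 0.0949, 0.0882 and 0.0908). They passed with all 9 libraries as separate samples (2.27, 1.42 and 1.89, adjusted p = 0.0325, 0.0299 and 0.0309) and without GSK503 replicate 2 (2.40, 1.55 and 1.95). Without replicates 1 and 4 they were 0.87, 0.70 and 0.70 and did not pass. On the list of interferon signalling components, 0 of 22 passed, 11 adjusted over the list alone, with a median of 0.64 (adjusted p = 5.11e-05, but adjusted p = 0.284 with an estimated correlation). The mean log2 CPM of the interferon-stimulated list was 6.04 in GSK503 replicates 1 and 4, 4.34 and 4.88 in replicates 2 and 3, and 3.86 to 4.50 in the vehicle libraries, so the groups overlapped. Without replicates 1 and 4 the list's median was 0.51, the interferon signalling median 0.32, the interferon gamma median 1.118, the MHC class II median 1.97 and the MHC class I median 0.67.

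**Figure D4:**
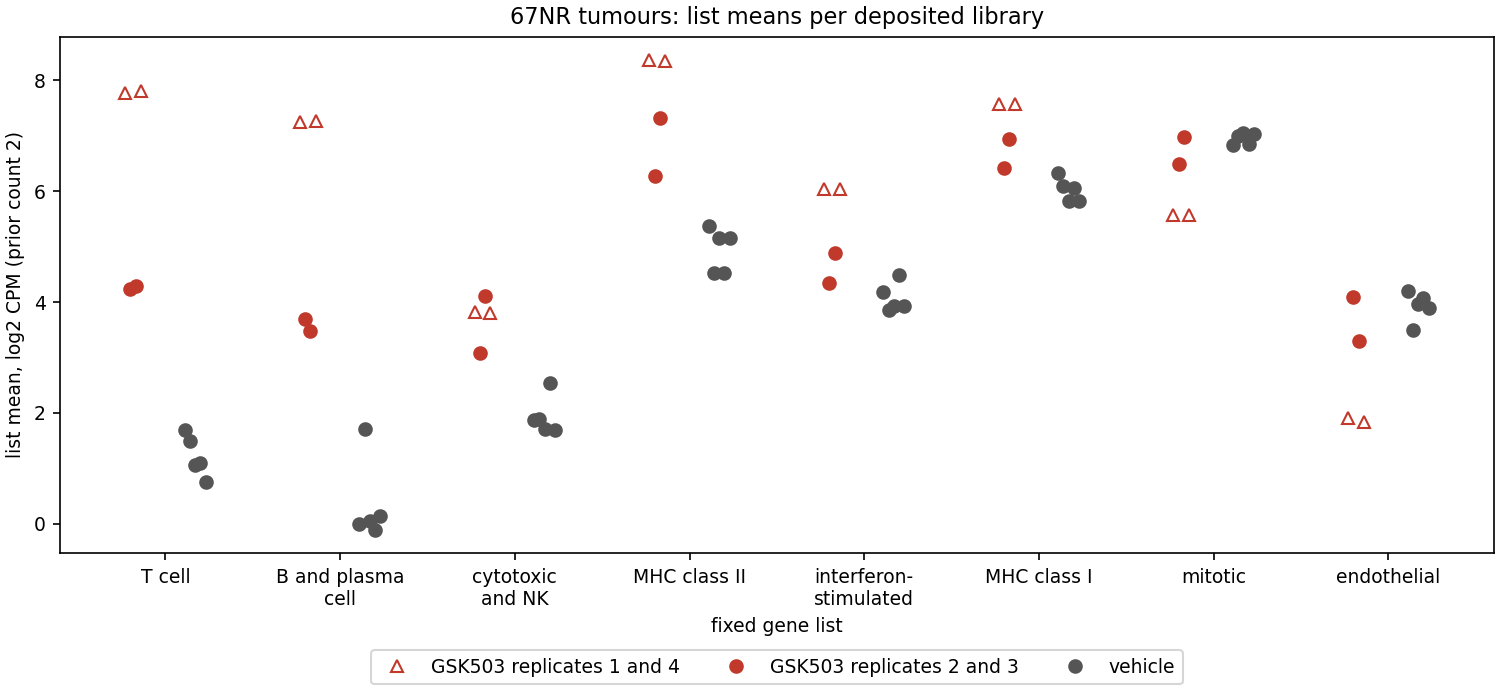
Mean log2 CPM (y axis, prior count 2) of 8 gene lists (x axis) in each deposited 67NR tumour library. GSK503 replicates 1 and 4 (open triangles) are highest for T cell genes, at 7.77 and 7.81, GSK503 replicates 2 and 3 (red points) stand at 4.23 and 4.29, and the vehicle libraries (grey points) at 0.76 to 1.69.

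Proliferation and endothelial genes were lower as groups in GSK503 tumours, with 0 members past the threshold, also adjusted over the list alone. The median log2 fold change was -0.47 for 30 mitotic genes (adjusted p = 4.39e-09), -0.35 for 33 DNA replication genes (adjusted p = 5.77e-06) and -0.63 for 18 endothelial markers (adjusted p = 0.000461), each with adjusted p = 0.434 with an estimated correlation. Among mitotic genes Aspm stood at -0.74 and Kif11 at -0.73, and among endothelial markers Cdh5 at -1.06 and Flt1 at -1.05. The mitotic list mean was 5.58 and 5.57 in GSK503 replicates 1 and 4, 6.50 and 6.98 in replicates 2 and 3, and 6.84 to 7.05 in the vehicle libraries, and the endothelial mean was 1.90 and 1.83, 4.09 and 3.29, and 3.49 to 4.19. Without replicates 1 and 4 the medians were -0.17, -0.15 and -0.25, and the endothelial list did not pass (adjusted p = 0.0917).

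Other tumour lists past the threshold upward were dendritic cell markers (1 of 15 rose, adjusted p = 2.3e-05), neutrophil markers (0 of 11, adjusted p = 0.0015), chemokines (1 of 26, adjusted p = 0.00512), NF-kB targets (2 of 21, adjusted p = 0.0129) and mammary epithelial markers (0 of 13, adjusted p = 0.0417). Adjusted over the list alone 5, 4, 4, 5 and 6 rose, and with an estimated correlation they gave adjusted p = 0.228, 0.284, 0.434, 0.434 and 0.354. Downward were developmental transcription factors (adjusted p = 1.47e-06), HOX genes (adjusted p = 0.000717) and epithelial-mesenchymal transition (adjusted p = 0.0329), with adjusted p = 0.472, 0.485 and 0.571 with an estimated correlation and 0 members that fell. Of the developmental factors 1 of 40 rose, Pax5, a B cell factor (6.33), chosen for mention after its value was seen. The developmental list mean was 2.45 and 2.58 in GSK503 replicates 1 and 4, 4.38 and 3.94 in replicates 2 and 3, and 3.90 to 4.59 with vehicle, and the median went from -0.66 to -0.25 without replicates 1 and 4 (adjusted p = 0.0361). The neutrophil and mammary medians went from 1.26 and 1.43 to 0.63 and 0.29 without them. In sum 20 of 32 mouse lists passed with the preset correlation and 0 with an estimated correlation. Chemokines no longer passed without GSK503 replicate 3 (adjusted p = 0.266). NF-kB targets were lost without GSK503 replicate 2 or 3 or vehicle replicate 4 (adjusted p = 0.0747, 0.24 and 0.0525). Mammary markers were lost without vehicle replicate 1, 4 or 5 (adjusted p = 0.0641, 0.0918 and 0.132). HOX genes were lost without GSK503 replicates 1 and 4 (adjusted p = 0.488), and epithelial-mesenchymal transition without them or without vehicle replicate 1 (adjusted p = 0.999 and 0.0783).

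Lists that did not pass were PRC2 and its partners (adjusted p = 0.139), cholesterol synthesis (0.139), fibroblasts and pericytes (0.141), skin (0.195), hypoxia and glycolysis (0.314), skeletal muscle (0.479), adipocytes (0.571), p53 targets (0.751), nerve (0.751), macrophages and monocytes (0.765), unfolded protein response (0.765) and immediate early genes (0.984). Of their members 1 macrophage marker and 1 immediate early gene rose and 0 others passed. Adjusted over the list alone, 2 nerve genes and 1 each of PRC2, macrophage, fibroblast, muscle and immediate early genes rose, and 1 fibroblast and 1 adipocyte marker fell. The median and the direction of the test differed in sign for fibroblasts, adipocytes, nerve and immediate early genes, and the mean and the test for fibroblasts, p53 targets, unfolded protein response, hypoxia and immediate early genes. Fibroblast markers passed downward without GSK503 replicate 3 (adjusted p = 0.00377), as did cholesterol synthesis without it or vehicle replicate 4 (0.00338 and 0.0212) and hypoxia genes without GSK503 replicate 3 (0.0492). Immediate early genes passed downward without vehicle replicate 4 (adjusted p = 0.0168) and upward without GSK503 replicates 1 and 4 (adjusted p = 0.00736), and their list mean was 5.17 in vehicle replicate 4 and 5.91 in both GSK503 replicates 1 and 4, against 8.92 and 8.74 in GSK503 replicates 2 and 3 and 8.47 to 8.95 in the other vehicle libraries. Red blood cell markers had too few tested members for a list test.

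The genes called higher in the tumours were not shared with those called higher in MCF7 beyond chance. Among 10163 genes tested in both, matched by symbol, 3843 rose in MCF7 and 101 in the tumours, and 36 rose in both where independence gives 38.2 (odds ratio 0.910, 95% interval 0.587 to 1.39, 2-sided Fisher's exact test p = 0.681, adjusted p = 1 over both directions). The only gene lower in the tumours, Skp2, was not lower in MCF7. Across genes the log2 fold changes had a Spearman's rho of 0.0220. The overlap covers only 101 of the 224 genes that rose in the tumours. On simulated data the tumour fit recovered 5.97% of 2-fold changes, so a moderate shared response could have been missed. Of 41 interferon-stimulated genes tested in both systems, 36 had a positive log2 fold change in each. Since 49 of 50 list members were positive in MCF7 and 52 of 55 in the tumours, a count near this follows from each list's own rise.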

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

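The tests of the T cell gap and of the B cell and cytotoxic shares (the latter by replicate) were chosen after seeing the results. So were those of hairpin off-target effects and of EZH2 mRNA between the hairpins. Tests of other sample splits and of gene length were chosen before, but not all of their settings. The splits used the tumour grouping settled after counts of genes under other groupings had been seen. Removal of the length trend, used for the interferon-stimulated list, was added after the data were seen.

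Lymphocyte genes were higher in GSK503 tumours, and most so in replicates 1 and 4. Of the 56 splits of the 8 samples into 3 and 5, only the real split (1) gave as many as 225 genes, and the highest other gave 5. This argues against chance only for the count at an adjusted p under 0.05, with vehicle replicates 3 and 5 as separate samples. Even for that count, 1 of 56 splits cannot exclude chance. At an unadjusted p under 0.05 in edgeR the real split gave 2100 genes. GSK503 replicates 1 and 4 grouped with GSK503 replicate 3 and vehicle replicate 4 gave more, 2690. By that measure the real split did not stand apart from chance. Vehicle replicates 3 and 5 differed by only 3.03, against 21.9 to 116 for other vehicle pairs. With them summed the count was 0 in edgeR (1486 at an unadjusted p under 0.05), and with any vehicle sample left out 0 or 1. Replicates 1 and 4 alone are argued against, because the lower of replicates 2 and 3 lay 2.54 log2 units above the highest vehicle library for the T cell list. Lymphoid tissue or RNA like that in replicates 1 and 4 may have contributed to B and T cell genes in replicates 2 and 3, since the excess over vehicle, as a share of the level in replicates 1 and 4, had a B to T ratio of 0.618 (95% interval over genes 0.436 to 1.34), which a treatment effect would also allow and so cannot be told apart. Were such tissue the whole source of the cytotoxic genes, their ratio to T cell genes would need to be about 0.5 to 2. The ratio was 6.76 (4.26 to 15.1) over both replicates. In replicate 3 it lay above that range (9.58, interval 5.87 to 24.2). In replicate 2 the interval over genes reached into that range (4.03, interval 1.80 to 9.39). These intervals cover the spread over genes in 1 library, not the variation between tumours. In vehicle replicate 4, Prf1 stood at 64.1 CPM, above the 49.9 and 45.4 of GSK503 replicates 1 and 4, though Nkg7 stood at 5.38. Such tissue as the whole source thus cannot be excluded in either replicate, and an inhibitor effect on lymphocytes stays open.

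The levels behind this pattern, for genes chosen after their values were seen, were 318, 16.0, 12.8 and 316 CPM of Cr2 (B cell complement receptor) and 2067, 240.2, 343 and 2025 CPM of Ptprc (CD45) in GSK503 replicates 1 to 4, against 0.571 to 4.43 and 54.0 to 145 CPM in the vehicle libraries. Gzmb, a granule protease, stood at 44.0, 29.2, 68.3 and 43.2 CPM against 9.88 to 45.2 with vehicle.

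Longer genes were lower in MCF7 libraries with EZH2 hairpins. Strongly changed and interferon genes are argued against as its source, since rho was -0.197 over the 13387 genes left without them. A difference in RNA or fragment length between the groups' libraries may underlie it and cannot be told apart from an effect of the hairpins: replicates differed with length by an absolute rho of at most 0.0478, but replicates that share an RNA would not show it. An effect of EZH2 on long genes was not tested. The trend does not account for the interferon-stimulated list, whose median log2 fold change was 3.09 with the trend removed.

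Interferon-stimulated genes rose with both EZH2 hairpins and more with shEZH24. An off-target effect of 1 hairpin as the whole cause is argued against, since 48 of the 50 members passed upward with each hairpin alone. Whether the size of the response follows EZH2 mRNA stays open, because EZH2 differed by only -0.012 log2 units between hairpins, while the interferon list differed. A reaction of the cells to a hairpin RNA that shCtrl does not provoke was not tested, so that release from EZH2 may be all, part or none of the response. In the tumours the interferon-stimulated list does not stand apart from chance, since 6 of the 56 splits gave a camera p as small as the real 4.18e-13, with 2.85e-18 the smallest of the others.

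The hairpins differed, by a test of the difference, for interferon-stimulated genes (adjusted p = 4.53e-36), MHC class I (3.53e-12) and immediate early genes (8.1e-13), and for oestrogen response genes (0.00111, with a median difference of -0.034, 0 members higher and 6 lower with shEZH24, 1 and 11 adjusted over the list alone), the last 2 not with an estimated correlation (0.122 and 0.343).

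Of 97 values tested for a library far from the rest of its group, 13 were, where chance gives about 1 in 20 (4.85) if the values are independent. They are not, since the B cell list holds Cd19, Fcer2a, Blk and Cd79b, and vehicle replicates 3 and 5 were close. The excess over 4.85 therefore cannot be read as beyond chance. In vehicle replicate 4 the list means (log2 CPM) were 2.55 for cytotoxic lymphocytes (others 1.70 to 1.89), 6.25 for hypoxia (5.46 to 5.66) and 5.17 for immediate early genes (8.47 to 8.95). Ezh2 stood at 38.2 CPM there (89.4 to 108) and Flt1 at 32.3 CPM (12.1 to 16.5). In vehicle replicate 2 the B cell list mean was 1.71 (others -0.11 to 0.14). The B cell genes Cd19 (4.39 CPM, others 0 to 0.573), Fcer2a (3.77, others 0 to 0.491), Blk (1.76, others 0.0844 to 0.327), Cd79b (1.26, others 0.507 to 0.656) and Dtx1 (1.13, others 0.131 to 0.245) were highest there. In vehicle replicate 1, Tnfrsf4 stood at 4.06 CPM (1.16 to 1.94) and Jchain at 0.787 CPM (0.0844 to 0.251).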

How the results depend on the processing

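The alternatives for the tumour libraries as deposited, for vehicle replicates 3 and 5 summed and for the length trend were chosen after the data were seen. EZH2 kept its fall in all 18 alternatives (log2 fold change -0.99 to -0.97), and the MCF7 interferon-stimulated list stayed past the threshold in all 14 (adjusted p from 1.7e-26 to 0.0249). With each library left out, MCF7 gave 8874 to 9496 genes. Of 1190 values for 70 named MCF7 genes, 1179 kept direction and call, as did 944 of 1329 for 61 tumour genes, 125 of 160 for the 10 genes of the hairpin difference, 266 of 294 for MCF7 lists and 504 of 589 for tumour lists. Scaling moved the median of all genes by at most 0.029 in size (-0.029). On simulated data the tumour comparison recovered 0% of 1.5-fold changes and 68.2% of 4-fold changes, and why it recovers fewer than MCF7 was not tested.

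An absolute log2 fold change of at least 1 left 1171 genes for both hairpins, 1242 for shEZH24, 1123 for shEZH2A, 958 shared and 13 between the hairpins, by construction. Between the hairpins an adjusted p under 0.01 left 202 genes, DESeq2 gave 140 and leaving out libraries 204 to 408. The 225 tumour genes became 0 at an adjusted p under 0.01 (2100 at an unadjusted p under 0.05), 696 with DESeq2, 1 with limma-voom, 434 with its quality weights and 838 with libraries as deposited. They became 0 in edgeR with vehicle replicates 3 and 5 summed too (1486 unadjusted), 68 when GSK503 replicates 1 and 4 were also left out, and 0 to 693 with each sample left out, where a vehicle sample left out gave 0 or 1. Leaving out GSK503 replicate 2 or 3, which also means fewer samples, gave 693 and 452. Those fits also change the spread within the GSK503 group, so they cannot show whether sample number accounts for the 0 or 1. The cause was not tested.

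Whether the replicate numbers pair the samples could not be told from the correlations between groups. Same-numbered tumours correlated at -0.334, 0.394, -0.00129 and 0.344, and 2 of 4 correlated best with their own number. The MCF7 libraries each matched their own number best, but at correlations of only 0.0022 to 0.019. GSK503 replicates 1 and 4, and the MCF7 libraries of each group, differed by little more than counting noise, which leaves such a test little to match. With the replicate number as a block, replicates 1 to 4 as deposited gave 2 genes, against 1 without the block.

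The tumour interferon-stimulated list had an adjusted p of 0.374 with an estimated correlation and 0.102 by fry (2.14e-14 to 8.8e-09 with samples left out). Lists past the threshold went from 13 to 1 for human and from 20 to 0 for mouse with an estimated correlation. By fry, which tests a list's own genes, they went to 19 for human and to 8 for mouse. The odds ratio of shared calls turned from 0.910 to 1.01 at a mean of at least 1 CPM and to 1.14 with libraries as deposited (Fisher's exact p = 0.185). Without GSK503 replicates 1 and 4 it was 0.662 (Fisher's exact p = 0.105). At an adjusted p under 0.01 the overlap had no tumour genes and gave no value.

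Values that changed sign were not past the threshold before the change, and after it only where stated, and ranges cover each sample left out in turn. EZH1 turned to 0.048 and 0.047 with the length trend removed, without and with the block, and without shEZH2A replicate 2 (range -0.079 to 0.016). IFNAR1 turned to -0.00365 with upper-quartile factors, and without shCtrl replicate 2 or shEZH24 replicate 1 (-0.018 to 0.036). Without GSK503 replicates 1 and 4, Suz12 (-0.00804 to 0.20) and Jak1 (-0.096 to 0.70) turned, and with vehicle 3 and 5 summed as well they stood at -0.058 and -0.088, and Pecam1 at -0.035. With quality weights Jak1 turned to -0.062. Of the MCF7 lists (adjusted p), fry turned PRC2 (0.00258) and developmental factors (0.0216) past the threshold, as it tests a list's own genes. HOX genes turned without shEZH24 replicate 2 (0.588 to 0.987) and with the length trend removed, without and with the block (0.497 and 0.57), and other cell types with a filter at 1 CPM (0.982).

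Of the tumour lists (adjusted p), those that turned without GSK503 replicates 1 and 4 were fibroblasts (0.00377 to 0.417), p53 targets (0.418 to 0.962), unfolded protein response (0.204 to 0.865, also without vehicle 1), hypoxia (0.0492 to 0.966) and immediate early genes (0.00736 to 0.807, also without vehicle 1, 2, 3 or 5), the last past the threshold upward without GSK503 replicates 1 and 4. With vehicle 3 and 5 summed as well, fibroblasts (0.241), p53 targets (0.561), cholesterol synthesis (0.946), unfolded protein response (0.298) and immediate early genes (0.00215, past the threshold) turned. Macrophages turned without GSK503 replicate 3, vehicle 1 or 2 (0.207 to 0.843), and adipocytes (0.402 to 0.975) and skeletal muscle (0.188 to 0.966) without vehicle 4. Adipocytes also turned as deposited (0.796), and with replicates 1 to 4 as deposited without and with the block (0.911 and 0.913), as did nerve without the block (1.00). Immediate early genes further turned with fry (0.908), RLE factors (0.975) and vehicle 3 and 5 summed (0.77). The cause was not tested.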

Other observations

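The lists and tests in this part were all chosen after the data were seen. Genes that respond to amino acid shortage, many of which the unfolded protein response also induces, were lower in MCF7 with both EZH2 hairpins. Of 32 tested, 30 fell and 1 rose, with a median log2 fold change of -0.89 (adjusted p = 1.88e-11 over the lists of this part, camera). They included ASNS, asparagine synthetase (-2.53), the cystine transporter SLC7A11 (-3.02), CHAC1 (-3.89), INHBE (-4.44), TRIB3 (-1.38) and the transcription factors ATF4 (-0.83) and DDIT3 (-0.99). With an estimated correlation the list gave an unadjusted p of 0.00645 (adjusted p = 0.0193). The list was chosen after CHAC1, ADM2 and SLC7A11 were seen among the largest decreases, so these p values restate that observation, and an independent test was not made.

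Ribosomal protein genes were slightly lower, with 69 of 80 past the threshold downward and 3 upward and a median of -0.26 (adjusted p = 2.91e-11, but adjusted p = 0.0983 with an estimated correlation), among them RPL3 (-0.58) and RPS6 (-0.47). The length trend as the source is argued against, because 1490 other genes of like length had a positive median of 0.13, and the sign of the ribosomal list held with RLE (-0.26) and upper-quartile factors (-0.27). Many ribosomal protein genes share reads with pseudogenes. Of 7 mucins, 4 fell and 3 rose (adjusted p = 0.207), with MUC5B (-2.24) and MUC16 (-3.19) lower and MUC1 (0.37) higher.

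In the tumours, markers of naive and follicular lymphocytes rose in 9 of 14 cases (median 5.62, adjusted p = 6.97e-14, but adjusted p = 0.0559 with an estimated correlation), and effector lymphocyte genes in 6 of 11 (median 2.27, adjusted p = 1.3e-10, and adjusted p = 0.0244 with an estimated correlation). The mean log2 CPM of the naive and follicular markers was 8.21 and 8.23 in GSK503 replicates 1 and 4, 4.57 and 4.25 in replicates 2 and 3, and 1.45 to 2.36 with vehicle, and of the effector genes 4.59 and 4.65, 3.45 and 4.43, and 2.03 to 2.68. The median of 5.62 therefore rests largely on replicates 1 and 4. Many of these genes also stand on the T cell, B cell or cytotoxic lists. The p-values of both lists therefore restate the rise of those lists, and an independent test was not made. Fn1, a matrix gene, stood at 1370 and 1347 CPM in GSK503 replicates 1 and 4, 4643 and 3225 in replicates 2 and 3, and 3589 to 9796 with vehicle.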
